A study of Mus musculus with 37 samples.

How the data were processed

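RNA was measured by sequencing in 37 libraries of BCR-ABL1-transformed mouse pre-B cells, in 10 groups defined by vector (MIG or MIG-IK6) and treatment (DMSO, ATRA, bexarotene, carbacyclin or NOE). Per the labels, RNA was extracted with Trizol, made into TruSeq RNA v2 libraries and sequenced on a HiSeq instrument. The authors' processing notes name BWA 0.5.9, HTSeq and the mouse build mm9, and the deposited values are raw counts per gene. Counting mode, strand setting and annotation release are not given in the sources used here. Reads of overlapping or antisense genes, and of genes with near-identical copies, may therefore be split between genes in an unknown way. Symbols and identifiers are those of the files, where 195 symbols occur more than once.

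Groups were taken from the labels. Total counts per library ran from 16.5 to 80.4 in units of 1000000, with a median of 35.1. Of 35290 genes in the files, 15699 were tested after edgeR's expression filter (minimum count 10, minimum total 15) and 19591 were not. The filter kept 99.97 to 99.99% of the counts of each library. Counts were scaled by the trimmed mean of M values and fitted with edgeR's robust quasi-likelihood model in 1 model of 10 groups with 27 residual degrees of freedom. The common dispersion was 0.0126, a biological coefficient of variation of 0.112. The median prior degrees of freedom were 4.63 and the prior count of fitted folds 0.125. Adjusted p-values are Benjamini-Hochberg over the tested genes of a comparison, with a threshold of 0.05, and the edgeR tests are two-sided. Intervals of log2 differences use the t distribution of the same model.

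The 15 comparisons were IK6 against MIG in DMSO, each of the 4 compounds against DMSO in each vector, the 4 interactions of vector and compound, and bexarotene against ATRA in each vector. Software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and matplotlib 3.10.9.

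The comparisons, the test, the alternatives, the gene lists and the rule for naming genes were chosen before the data were examined. The rule took the genes with the largest rises and falls among those past the threshold, with a mean of at least 1 CPM in a compared group and no overlap between the libraries of the groups (for interactions without the last criterion). It took 6 each way for IK6 against MIG, ATRA and bexarotene, and 3 each way elsewhere. It added up to 4 members of each list with the smallest adjusted p, and 20 genes that could always be named. The text names a part of these genes and leaves out predicted genes without a name.

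The 22 lists hold retinoic acid response genes, LXR and RXR target genes of cholesterol efflux and lipid synthesis, PPAR target genes of fatty acid oxidation, retinoid and lipid nuclear receptor genes, Ikaros family and B-lineage transcription factors, pre-B cell receptor and B-lineage genes, stem and progenitor cell genes, integrin and cell adhesion genes, cell cycle S and G2/M genes, cell cycle inhibitor and quiescence genes, MYC target genes, BCL2 family apoptosis genes, JAK-STAT and ERK feedback genes, cholesterol synthesis genes, glycolysis and glucose uptake genes, interferon response genes, MHC class II genes, integrated stress response and heat shock genes, myeloid markers, T and NK cell markers, erythroid and megakaryocyte markers, and stromal and endothelial markers. Each was tested with limma's camera at its preset correlation of 0.01, adjusted over the 22 lists of a comparison, and again with an estimated correlation and with fry. A list of 18 hypoxia genes outside the glycolysis list was added later.

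For genes with 0 counts in a group, folds are bounds against a floor of 3 counts over the group. With 1 to 3 counts, the ratio of pooled counts is given with its exact 95% binomial interval. Shared genes between comparisons were counted by direction, set against the number 2 independent responses would give, and, where comparisons share libraries, against 10 draws of simulated unchanged groups and 3 ways of halving the controls. The vector was checked with an exact permutation test.

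On counts simulated with the library sizes and dispersions of ATRA in MIG, with 200 of 15699 genes changed, the test found 46 of 67 genes changed 1.5-fold, 64 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 4 false calls among 15499 unchanged genes. Changed genes had a mean of at least 1 CPM in MIG with DMSO, and counts were drawn independently between genes. The real comparison called 6566 genes, so these rates may not hold for it. No library repeated another: over 51 pairs within groups, chi-square per degree of freedom ran from 2.56 to 289.

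Alternatives were DESeq2, other scalings, other filters, fits of the compared groups alone, replicate numbers as a block, and leaving out each library in turn. Chosen after seeing the data were leaving out 3 libraries with a ribosomal protein share above 12%, that share as a covariate, and the overlap of carbacyclin and NOE.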

Results

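RNA sequencing counted reads over genes in pre-B cells that had been grown from the bone marrow of adult C57BL/6 mice lacking Arf and transformed with BCR-ABL1, the fusion kinase of Philadelphia chromosome leukemia. Cells carried either an empty vector expressing green fluorescent protein (MIG) or the same vector expressing IK6, a dominant-negative isoform of the transcription factor IKAROS (MIG-IK6). Each was treated with the solvent DMSO or with 1 µM of 1 of 4 compounds: all-trans retinoic acid (ATRA), bexarotene, carbacyclin or N-oleoylethanolamine (NOE). ATRA is the natural ligand of the retinoic acid receptors, bexarotene a synthetic ligand of the retinoid X receptors, carbacyclin a prostacyclin analog and NOE a fatty acid amide. The time of treatment is not given in the sources used here.

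The 37 libraries formed 10 groups of 4, except that bexarotene in MIG, bexarotene in IK6 and carbacyclin in IK6 had 3. Total counts per library, in units of 1000000, ran from 29.4 to 48 in MIG with DMSO, 16.5 to 34.2 with ATRA, 26.4 to 48.5 with bexarotene, 18.5 to 69 with carbacyclin and 29 to 49.7 with NOE. In IK6 they ran from 30.3 to 44.7 with DMSO, 25.2 to 80.4 with ATRA, 17.4 to 47.1 with bexarotene, 26.4 to 38.2 with carbacyclin and 31 to 63.8 with NOE. Ribosomal protein genes took 7.49 to 11.8% of counts in 34 libraries and more in 3 MIG libraries: 15.82% in carbacyclin replicate 4, 15.71% in DMSO replicate 3 and 12.75% in bexarotene replicate 3. Expression values are means ± SD of counts per 1000000 (CPM) over the libraries of a group, and differences are log2 fold changes ± SE. For each gene list, members counted neither up nor down did not pass the test. The number over the list alone counts members called when p is adjusted over that list. The adjusted p is that of camera with a preset correlation, and a call printed with that p alone held with an estimated correlation. Where replicate blocks or, chosen after seeing the data, leaving out these 3 libraries or ribosomal protein share as a covariate ended a list call, that adjusted p follows. The labels do not say whether replicates are separate cultures, so p-values measure the spread between these samples, which may be technical. Counting intervals and lower bounds on folds cover counting error only.

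Over the 1000 most variable genes, the first principal component held 47.1% of the variance and parted IK6 from MIG libraries. The second held 20.3% and set ATRA and bexarotene apart from carbacyclin and NOE.

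**Figure D1:**
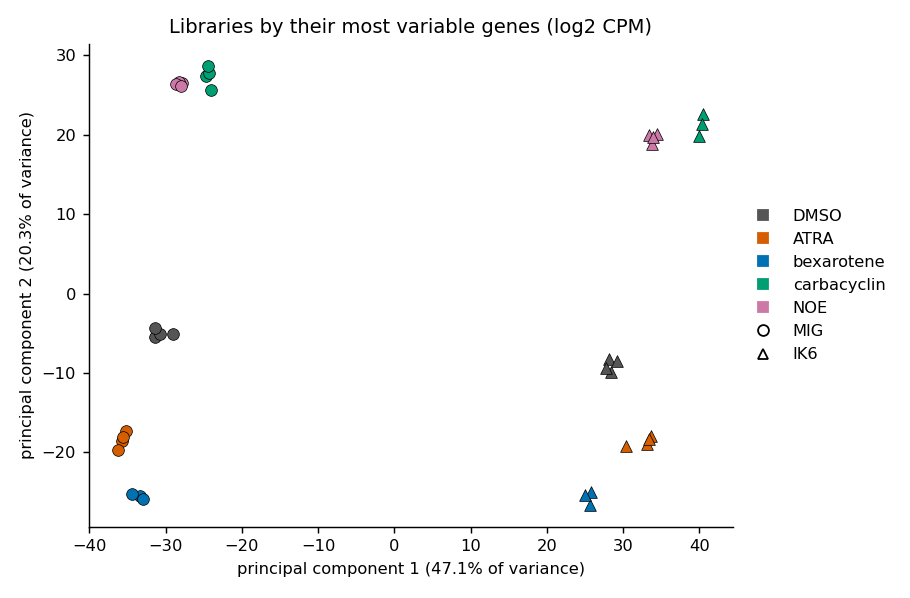
Scores of the 37 libraries on the first principal component (x axis, 47.1% of variance) and the second (y axis, 20.3%) of log2 CPM over 1000 genes. Each point is a library, with the vector given by the marker and the treatment by the colour.

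The vector and the genotype were checked first. Ikzf1 (ENSMUSG00000018654), the gene of IKAROS, stood at 264 ± 6.07 CPM in MIG and 424 ± 10.7 CPM in IK6 with DMSO, a ratio of 1.61. Every IK6 library lay above every MIG library there (exact two-sided permutation test over 70 splits, p = 0.0286, the smallest it can give). The IK6 mean was also the higher one with ATRA (508 ± 29.5 against 293 ± 16.6 CPM), bexarotene (485.5 ± 41.9 against 357 ± 6.2), carbacyclin (463 ± 18.4 against 234 ± 12.7) and NOE (382 ± 23.9 against 228 ± 20). Gene-level counts do not separate the vector's transcript from the cells' own. Cdkn2a (ENSMUSG00000044303), the locus of both p16Ink4a and Arf, whose exons these counts do not tell apart, kept counts in all 10 groups, with means from 65.6 ± 21.4 CPM (MIG with bexarotene) to 132 ± 29.9 CPM (IK6 with NOE).

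**Figure D2:**
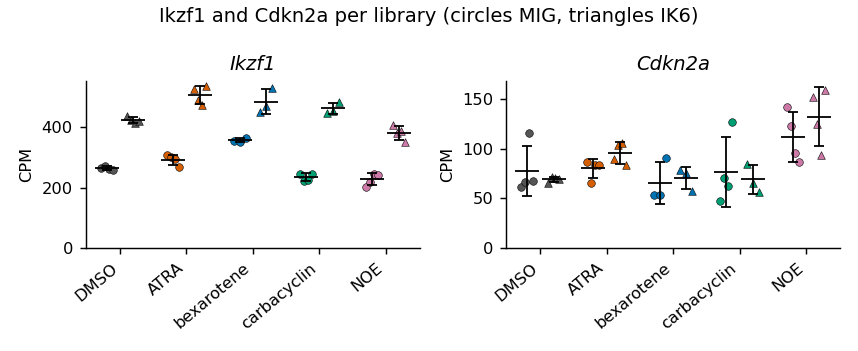
CPM of Ikzf1 and Cdkn2a (y axes) in each library of the 10 groups (x axes). Circles are MIG and triangles IK6, bars the group mean and whiskers the SD; Ikzf1 averages 264 CPM in MIG and 424 CPM in IK6 with DMSO.

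IK6 cells were compared with MIG cells in DMSO. Effects of IK6 and of any clonal difference cannot be told apart. Among adhesion genes 13 of 28 rose, among progenitor genes 6 of 11 and among T and NK cell genes 4 of 9. Itga5 (ENSMUSG00000000555), a chain of the fibronectin receptor, rose from 0.225 ± 0.0213 to 20.8 ± 0.285 CPM, Thy1 (ENSMUSG00000032011), a T cell and progenitor surface gene, from 1.25 ± 0.232 to 23.1 ± 1.35 CPM, and Ccr2 (ENSMUSG00000049103), a monocyte chemokine receptor, from 2.51 ± 0.146 to 38.1 ± 1.87 CPM. Kit (ENSMUSG00000005672), the stem cell factor receptor, had 0 counts in the 4 MIG libraries and 0.620 ± 0.0634 CPM in IK6, at least 27.6-fold higher when set against 3 counts over the group. Interferon response genes fell (17 of 23), and of glycolysis genes 19 of 21 fell, a list call lost with an estimated correlation (adjusted p = 0.17). Also lower were Il2ra (ENSMUSG00000026770), a pre-B surface marker (from 39.9 ± 1.54 to 8.78 ± 0.463 CPM), the survival gene Bcl2 (ENSMUSG00000057329) (from 207 ± 27.1 to 66.6 ± 5.65 CPM) and Dusp4 (ENSMUSG00000031530), a phosphatase of ERK (from 84.5 ± 2.15 to 15.9 ± 0.624 CPM).

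Of integrin and cell adhesion genes, 13 of 28 rose and 6 fell (23 over the list alone, adjusted p = 5.96e-07). Itgb7 (ENSMUSG00000001281), an integrin chain, changed by -1.90 ± 0.125 on the log2 scale. Of stem and progenitor cell genes, 6 of 11 rose and 2 fell (10 over the list alone, adjusted p = 0.0094, 0.0649 with the covariate), with log2 changes of 1.96 ± 0.111 for Angpt1 (ENSMUSG00000022309), 2.36 ± 0.179 for Tal1 (ENSMUSG00000028717) and -1.62 ± 0.18 for Ly6a (ENSMUSG00000075602). Of T and NK cell markers, 4 of 9 rose and 0 fell (5 over the list alone, adjusted p = 1.29e-06). Cd5 (ENSMUSG00000024669) changed by 3.26 ± 0.161 and Klrd1 (ENSMUSG00000030165) by 2.49 ± 0.262. Of myeloid markers, 3 of 12 rose and 3 fell (6 over the list alone, adjusted p = 0.0452, adjusted p = 0.147 with an estimated correlation, 0.0682 with replicate blocks, 0.0636 without the 3 libraries, 0.0649 with the covariate). Lyz2 (ENSMUSG00000069516), lysozyme, changed by 2.26 ± 0.29, and the ratio of MIG to IK6 was 42 (11.2 to 353) for Ly6c2 (ENSMUSG00000022584). Of cell cycle S and G2/M genes, 18 of 30 rose and 0 fell (20 over the list alone, adjusted p = 6.54e-05, adjusted p = 0.478 with an estimated correlation), with Ccna2 (ENSMUSG00000027715), cyclin A2, changing by 0.44 ± 0.0626. Of glycolysis and glucose uptake genes, 0 of 21 rose and 19 fell (21 over the list alone, adjusted p = 1.28e-08, adjusted p = 0.17 with an estimated correlation). Pdk1 (ENSMUSG00000006494) changed by -0.62 ± 0.0747 and Slc16a3 (ENSMUSG00000025161), a lactate exporter, by -1.31 ± 0.15. Of interferon response genes, 2 of 23 rose and 17 fell (20 over the list alone, adjusted p = 1.2e-05). Irf7 (ENSMUSG00000025498) changed by -1.91 ± 0.18 and Mx1 (ENSMUSG00000000386) by -2.72 ± 0.251.

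The other lists were not called as sets. Of pre-B cell receptor and B-lineage genes, 3 of 20 rose and 6 fell (9 over the list alone, adjusted p = 0.0719), with Syk (ENSMUSG00000021457) changing by -0.50 ± 0.0452, Rag1 (ENSMUSG00000061311), a recombinase gene, by 1.06 ± 0.0977 and Il7r (ENSMUSG00000003882) by 0.84 ± 0.0919. Of Ikaros family and B-lineage transcription factors, 3 of 18 rose and 4 fell (8 over the list alone, adjusted p = 0.626). Besides Ikzf1, Spib (ENSMUSG00000008193) changed by -0.81 ± 0.0548 and Ikzf3 (ENSMUSG00000018168) by 0.51 ± 0.123, while Ikzf2 (ENSMUSG00000025997) was at 0.173 ± 0.009 CPM in IK6 and 0.124 ± 0.111 CPM in MIG (adjusted p = 0.398). Of JAK-STAT and ERK feedback genes, which answer signalling by BCR-ABL1, 6 of 22 rose and 8 fell (15 over the list alone, adjusted p = 0.435). Pim2 (ENSMUSG00000031155) changed by -1.80 ± 0.0963, Ccnd1 (ENSMUSG00000070348), cyclin D1, by 1.39 ± 0.0636 and Egr1 (ENSMUSG00000038418) by 2.13 ± 0.116. Of retinoid and lipid nuclear receptor genes, 3 of 13 rose and 4 fell (8 over the list alone, adjusted p = 0.762). Rxra (ENSMUSG00000015846), a retinoid X receptor, changed by 2.00 ± 0.0898 and Rara (ENSMUSG00000037992), a retinoic acid receptor, by -0.79 ± 0.103. Of BCL2 family apoptosis genes, 2 of 13 rose and 3 fell (5 over the list alone, adjusted p = 0.626). Of erythroid and megakaryocyte markers, 1 of 10 rose and 1 fell (2 over the list alone, adjusted p = 0.762), and of stromal and endothelial markers, 0 of 5 rose and 1 fell (1 over the list alone, adjusted p = 0.617).

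In all, 4079 genes passed the threshold (2081 up, 1998 down, 1118 by at least 2-fold). Among genes near 0 in 1 vector, ratios of pooled counts, here and below with 95% counting intervals in parentheses, were 528 (94.5 to 20900) for Xlr3b (ENSMUSG00000073125), 319 (56.9 to 12600) for Gprc5c (ENSMUSG00000051043), 300 (53.5 to 11900) for Lmo1 (ENSMUSG00000036111), an oncogene of T cell leukemia, 255 (45.4 to 10100) for Rps6ka6 (ENSMUSG00000025665), 173 (58.8 to 840) for Dock1 (ENSMUSG00000058325) and 142 (48.5 to 693) for Igf2 (ENSMUSG00000048583), all higher in IK6. Higher in MIG were Ighv15-2 (ENSMUSG00000076688) and Ighv2-7 (ENSMUSG00000076647), heavy chain V segments, with ratios of 1040 (288 to 8620) and 76.5 (25.8 to 374). Log2 changes were -7.42 ± 0.374 for Ighv2-6-8 (ENSMUSG00000076646), -6.27 ± 0.254 for the collagen gene Col5a2 (ENSMUSG00000026042), -6.20 ± 0.216 for Aldh1a7 (ENSMUSG00000024747) and -5.83 ± 0.369 for Slc16a14 (ENSMUSG00000026220). V segments and Xlr3b share sequence with near copies, so their values are uncertain. With the covariate 6626 genes passed.

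ATRA was compared with DMSO in each vector to find the genes that answer a ligand of the retinoic acid receptors. Of retinoic acid response genes 9 of 16 rose in MIG and 7 in IK6, and of LXR target genes 11 of 14 in each. Cell cycle genes fell in MIG (28 of 30) and in IK6 (29). Cd38 (ENSMUSG00000029084), a retinoic acid target, rose from 98.6 ± 2.63 to 762 ± 45.2 CPM in MIG and from 123 ± 6.23 to 600.3 ± 14.3 CPM in IK6. Cyp26a1 (ENSMUSG00000024987), the enzyme that degrades retinoic acid, rose from 0.134 ± 0.0497 to 4.97 ± 0.527 CPM in MIG and from 0.0833 ± 0.0256 to 1.62 ± 0.111 CPM in IK6. Abcg1 (ENSMUSG00000024030), a cholesterol exporter, rose from 39.9 ± 1.28 to 254 ± 9.99 CPM in MIG and from 28.0 ± 2.12 to 236 ± 8.08 CPM in IK6, and Cdkn1a (ENSMUSG00000023067), the cell cycle inhibitor p21, from 47.6 ± 6.74 to 218 ± 15 CPM in MIG and from 57.3 ± 2.36 to 182 ± 9.26 CPM in IK6.

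Of retinoic acid response genes, 9 of 16 rose and 2 fell (12 over the list alone, adjusted p = 3.86e-11) in MIG. In IK6, 7 rose and 2 fell (10 over the list alone, adjusted p = 3.86e-09). Tgm2 (ENSMUSG00000037820), transglutaminase 2, changed by 3.59 ± 0.132 in MIG and 2.60 ± 0.124 in IK6 on the log2 scale, Asb2 (ENSMUSG00000021200) by 3.22 ± 0.112 in IK6 and Dhrs3 (ENSMUSG00000066026), a retinal reductase, by 0.80 ± 0.118 in MIG. Rarb (ENSMUSG00000017491) was at 0.771 ± 0.278 CPM with ATRA and 0.505 ± 0.184 CPM with DMSO in MIG (adjusted p = 0.0958; 0.427 in IK6), and passed only without MIG DMSO replicate 1 (adjusted p = 0.0289). Cyp26b1 (ENSMUSG00000063415) was not tested, with 39 counts over 37 libraries. Of LXR and RXR target genes of cholesterol efflux and lipid synthesis, 11 of 14 rose and 0 fell (11 over the list alone, adjusted p = 3.21e-24) in MIG. In IK6, 11 rose and 1 fell (12 over the list alone, adjusted p = 1.66e-24). Scd1 (ENSMUSG00000037071), a fatty acid desaturase, changed by 1.89 ± 0.076 in MIG and 2.32 ± 0.0772 in IK6, Mylip (ENSMUSG00000038175) by 2.22 ± 0.044 in MIG and 1.76 ± 0.0432 in IK6 and Srebf1 (ENSMUSG00000020538), a regulator of lipid synthesis, by 0.83 ± 0.0759 in MIG and 1.03 ± 0.0761 in IK6. Of cell cycle genes, 1 of 30 rose and 28 fell (29 over the list alone, adjusted p = 4.24e-31) in MIG. In IK6, 0 rose and 29 fell (30 over the list alone, adjusted p = 4.59e-33). Ccna2 changed by -1.69 ± 0.0652 in MIG and -1.88 ± 0.0649 in IK6. Of interferon response genes, 21 of 23 rose and 0 fell (21 over the list alone, adjusted p = 2.05e-16) in MIG. In IK6, 20 rose and 1 fell (22 over the list alone, adjusted p = 2.67e-08). Irf9 (ENSMUSG00000002325) changed by 0.74 ± 0.0523 in MIG and 0.52 ± 0.0521 in IK6.

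Of pre-B and B-lineage genes, 11 of 20 rose and 0 fell (11 over the list alone, adjusted p = 3.53e-07) in MIG. In IK6, 12 rose and 3 fell (15 over the list alone, adjusted p = 0.00655, adjusted p = 0.204 with an estimated correlation). Ms4a1 (ENSMUSG00000024673), the gene of CD20, changed by 2.59 ± 0.142 in MIG and 2.58 ± 0.155 in IK6 and Syk by 1.01 ± 0.0455 in MIG. Of MHC class II genes, 9 of 10 rose and 0 fell (9 over the list alone, adjusted p = 0.00525, adjusted p = 0.327 with an estimated correlation) in MIG. In IK6, 8 rose and 0 fell (8 over the list alone, adjusted p = 3.54e-05, adjusted p = 0.139 with an estimated correlation). Cd74 (ENSMUSG00000024610), the invariant chain, changed by 1.33 ± 0.104 in MIG and 2.22 ± 0.107 in IK6. Of PPAR target genes of fatty acid oxidation, 7 of 18 rose and 3 fell (11 over the list alone, adjusted p = 0.0061, adjusted p = 0.411 with an estimated correlation) in MIG. In IK6, 10 rose and 2 fell (12 over the list alone, adjusted p = 1.61e-05, adjusted p = 0.204 with an estimated correlation). The median log2 change of this list in MIG was -0.067, opposite in sign to its test, and Cpt1a (ENSMUSG00000024900), the rate-limiting enzyme of the pathway, changed by 1.51 ± 0.0503 in MIG and 1.42 ± 0.05 in IK6. Pdk4 (ENSMUSG00000019577), an inhibitory kinase of pyruvate dehydrogenase, had 0 counts with DMSO in MIG and 0.114 ± 0.037 CPM with ATRA, at least 5.05-fold higher. In MIG, of MYC target genes 0 of 20 rose and 16 fell (16 over the list alone, adjusted p = 3.05e-07, adjusted p = 0.137 with an estimated correlation). Of integrated stress response and heat shock genes there, 4 of 20 rose and 12 fell (17 over the list alone, adjusted p = 0.00301, adjusted p = 0.384 with an estimated correlation), and of cell cycle inhibitor and quiescence genes 7 of 17 rose and 2 fell (10 over the list alone, adjusted p = 0.0364, adjusted p = 0.327 with an estimated correlation). Asns (ENSMUSG00000029752), asparagine synthetase, changed by -2.02 ± 0.108 in MIG and -1.26 ± 0.105 in IK6. In IK6, T and NK cell markers were called downward (adjusted p = 0.0179, 0.0568 without the 3 libraries).

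With ATRA, 6566 genes passed the threshold (3233 up, 3333 down, 1370 by at least 2-fold) in MIG and 6837 genes passed the threshold (3557 up, 3280 down, 1455 by at least 2-fold) in IK6. Among the largest changes, Tspan15 (ENSMUSG00000037031), a tetraspanin, rose from 1.40 ± 0.323 to 315 ± 15 CPM in MIG and from 0.940 ± 0.189 to 248 ± 10.1 CPM in IK6, and Mmp9 (ENSMUSG00000017737), a matrix metalloprotease, from 0.0355 ± 0.028 to 9.06 ± 2.05 CPM in MIG and from 0.227 ± 0.052 to 76.0 ± 1.95 CPM in IK6. Abca1 (ENSMUSG00000015243), a cholesterol exporter, changed by 7.60 ± 0.305 in MIG and 5.99 ± 0.236 in IK6, and in MIG Ngfr (ENSMUSG00000000120), a neurotrophin receptor, by 6.59 ± 0.292 and Hic1 (ENSMUSG00000043099) by 5.56 ± 0.253. The ratio was 199 (35.2 to 7890) for Mras (ENSMUSG00000032470) in MIG and 206 (36.6 to 8170) for Pdk4 in IK6, and Clec7a (ENSMUSG00000079293), a receptor of fungal glucans, had 0 counts with DMSO in IK6 and 2.86 ± 0.584 CPM with ATRA, at least 148-fold higher. Falls in MIG were -3.11 ± 0.136 for Mc1r (ENSMUSG00000074037), a melanocortin receptor, -3.22 ± 0.258 for the T cell costimulator Cd28 (ENSMUSG00000026012), -2.56 ± 0.221 for Trav14d-2 (ENSMUSG00000076787), -2.50 ± 0.317 for Kcnh1 (ENSMUSG00000058248) and -2.44 ± 0.24 for Cpeb1 (ENSMUSG00000025586). In IK6 they were -5.95 ± 0.371 for Slc35d3 (ENSMUSG00000050473), -4.28 ± 0.276 for the T cell gene Cd6 (ENSMUSG00000024670), -3.70 ± 0.206 for Enthd1 (ENSMUSG00000050439), -3.29 ± 0.284 for Cpeb1 and -3.79 ± 0.973 for Hist1h2af (ENSMUSG00000061991). Trav14d-2 and Hist1h2af have near copies, so their values are uncertain.

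The interaction of vector and ATRA asks which responses differ between IK6 and MIG. MYC target genes had a higher response in IK6 (13 of 20), and Myc itself fell in MIG. Myc (ENSMUSG00000022346) went from 296 ± 10.9 to 128 ± 3.55 CPM in MIG and from 255 ± 13.2 to 285 ± 5.54 CPM in IK6, a log2 difference between the responses of 1.37 ± 0.0789. Of MYC target genes, 13 of 20 were shifted up and 0 down (19 over the list alone, adjusted p = 2.52e-20), with a median of 0.53. Nolc1 (ENSMUSG00000015176) differed by 0.53 ± 0.0668. Of pre-B and B-lineage genes, 1 of 20 were shifted up and 6 down (8 over the list alone, adjusted p = 0.000806, adjusted p = 0.295 with an estimated correlation). Syk, which rose in both vectors, differed by -0.70 ± 0.0639. Of stress response genes, 9 of 20 were shifted up and 1 down (14 over the list alone, adjusted p = 5.11e-05, adjusted p = 0.447 with an estimated correlation). Of JAK-STAT and ERK genes, 6 of 22 were shifted up and 2 down (14 over the list alone, adjusted p = 0.00326, adjusted p = 0.447 with an estimated correlation). Ccnd1 went from 48.5 ± 1.77 to 33.5 ± 1.79 CPM in MIG and from 127 ± 4.66 to 173 ± 2.51 CPM in IK6. Of quiescence genes, 0 of 17 were shifted up and 2 down (4 over the list alone, adjusted p = 0.0481, adjusted p = 0.447 with an estimated correlation, 0.0538 with replicate blocks). Cdkn1a differed by -0.53 ± 0.15. In all, 1536 genes differed, 839 of them (54.6%) with the higher response in IK6. That share fell to 43.9% with CPM above 1, 49.1% with upper-quartile scaling and 47.3 to 49.2% without MIG DMSO replicate 1, 2 or 4 or any MIG ATRA library. The genes include Gas7 (ENSMUSG00000033066) (2.58 ± 0.14), the embryonic globin Hbb-bh1 (ENSMUSG00000052217) (3.11 ± 0.316), Igfbp5 (ENSMUSG00000026185) (3.42 ± 0.501), Enthd1 (-3.77 ± 0.238), the growth factor receptor Egfr (ENSMUSG00000020122) (-3.39 ± 0.633) and Slc35d3 (-3.81 ± 0.828). Fitting only the 4 groups compared gave 2530 genes and the ribosomal protein covariate 2713.

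**Figure D3:**
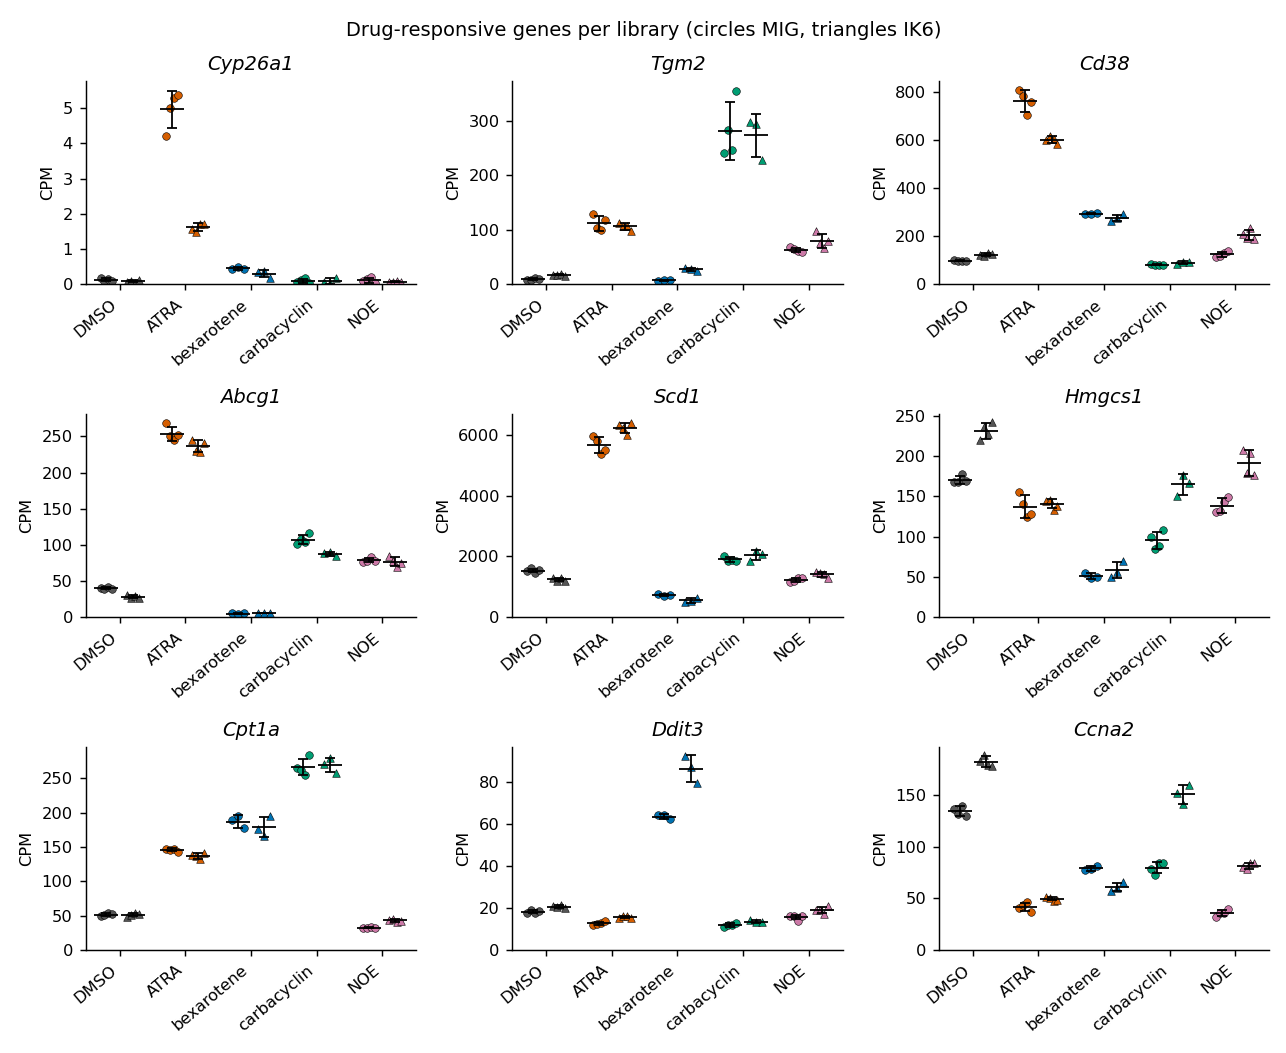
CPM (y axes) of 9 genes in each library of the 10 groups (x axes). Circles are MIG, triangles IK6, bars the group mean and whiskers the SD, and Abcg1 averages 254 CPM with ATRA and 4.88 CPM with bexarotene in MIG, against 39.9 CPM with DMSO.

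Bexarotene was compared with DMSO to find the genes that answer a ligand of the retinoid X receptors. Cholesterol synthesis genes fell (20 of 20 in both vectors), and 11 of 20 stress response genes rose in each while 3 fell in MIG and 2 in IK6, list calls lost with an estimated correlation (adjusted p = 0.118 and 0.0769). Abcg1 fell from 39.9 ± 1.28 to 4.88 ± 0.253 CPM in MIG and from 28.0 ± 2.12 to 5.67 ± 0.182 CPM in IK6. Hmgcs1 (Hmgcs1.NT_110857.n), an early enzyme of cholesterol synthesis, fell from 171 ± 5.01 to 51.2 ± 3.69 CPM in MIG and from 232 ± 10.1 to 58.6 ± 10 CPM in IK6. Ddit3 (ENSMUSG00000025408), the stress transcription factor CHOP, rose from 18.2 ± 0.683 to 63.6 ± 1.11 CPM in MIG and from 20.6 ± 0.689 to 86.5 ± 6.34 CPM in IK6, and Ms4a1 from 2.05 ± 0.137 to 51.4 ± 7.55 CPM in MIG and from 0.943 ± 0.283 to 14.3 ± 1.17 CPM in IK6.

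Of cholesterol synthesis genes, 0 of 20 rose and 20 fell (20 over the list alone, adjusted p = 4.82e-31) in MIG. In IK6, 0 rose and 20 fell (20 over the list alone, adjusted p = 9.72e-29), with medians of -1.11 and -1.14. Of LXR and RXR target genes, 0 of 14 rose and 8 fell (8 over the list alone, adjusted p = 7.47e-12) in MIG. In IK6, 2 rose and 10 fell (13 over the list alone, adjusted p = 2.41e-09). Scd1 changed by -1.08 ± 0.0818 in MIG and -1.18 ± 0.0821 in IK6 and Srebf1 by -0.95 ± 0.0837 in MIG and -0.73 ± 0.0833 in IK6. Of stress response genes, 11 of 20 rose and 3 fell (15 over the list alone, adjusted p = 1.14e-07, adjusted p = 0.118 with an estimated correlation) in MIG. In IK6, 11 rose and 2 fell (14 over the list alone, adjusted p = 2.41e-09, adjusted p = 0.0769 with an estimated correlation). Trib3 (ENSMUSG00000032715), a stress-induced pseudokinase, changed by 2.05 ± 0.101 in MIG and 2.26 ± 0.101 in IK6. Of PPAR target genes, 7 of 18 rose and 4 fell (11 over the list alone, adjusted p = 0.000173, adjusted p = 0.178 with an estimated correlation) in MIG. In IK6, 8 rose and 4 fell (12 over the list alone, adjusted p = 8.51e-07, adjusted p = 0.116 with an estimated correlation). The median of this list in MIG, -0.043, was opposite in sign to its test. Cpt1a changed by 1.87 ± 0.0531 in MIG and 1.80 ± 0.053 in IK6, and Cd36 (ENSMUSG00000002944), a fatty acid transporter, by 3.52 ± 0.132 in MIG and 2.68 ± 0.12 in IK6. Of pre-B and B-lineage genes, 10 of 20 rose and 3 fell (14 over the list alone, adjusted p = 1.05e-05, adjusted p = 0.061 with an estimated correlation) in MIG. In IK6, 12 rose and 3 fell (17 over the list alone, adjusted p = 0.00042, adjusted p = 0.086 with an estimated correlation). Rag1 changed by 2.00 ± 0.103 in MIG and 1.37 ± 0.0982 in IK6 and Dntt (ENSMUSG00000025014), terminal transferase, by -2.10 ± 0.13 in MIG and -2.06 ± 0.128 in IK6.

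Of cell cycle genes, 2 of 30 rose and 18 fell (21 over the list alone, adjusted p = 1.01e-08, adjusted p = 0.178 with an estimated correlation) in MIG. In IK6, 0 rose and 28 fell (29 over the list alone, adjusted p = 9.72e-29). Of glycolysis genes, 0 of 21 rose and 21 fell (21 over the list alone, adjusted p = 4.59e-13, adjusted p = 0.0765 with an estimated correlation) in MIG. In IK6, 1 rose and 11 fell (13 over the list alone, adjusted p = 0.0287, adjusted p = 0.517 with an estimated correlation). A further 5 lists were called in MIG, upward for quiescence genes, interferon response genes and MHC class II genes and downward for MYC target genes and JAK-STAT and ERK genes (adjusted p = 2.97e-05 to 0.0335; adjusted p = 0.061 to 0.323 with an estimated correlation). A further 7 lists were called in IK6, upward for quiescence genes, interferon response genes, MHC class II genes and stromal and endothelial markers and downward for adhesion genes, MYC target genes and T and NK cell markers (adjusted p = 0.0043 to 0.0481; adjusted p = 0.086 to 0.385 with an estimated correlation for all but T and NK cell markers). Calls lost under an alternative were those of quiescence genes (0.0519 with the covariate) and stromal and endothelial markers (0.0833 without the 3 libraries, 0.0825 with the covariate). Btg2 (ENSMUSG00000020423), an antiproliferative gene, changed by 1.62 ± 0.0852 in MIG and 1.55 ± 0.0851 in IK6, Myc by -1.06 ± 0.0617 in MIG and -0.32 ± 0.0604 in IK6 and Cd74 by 1.95 ± 0.111 in MIG and 1.75 ± 0.111 in IK6. The retinoic acid response genes were not called as a set. Of them 5 of 16 rose and 4 fell (9 over the list alone, adjusted p = 0.187) in MIG. In IK6, 5 rose and 2 fell (8 over the list alone, adjusted p = 0.0896). Cd38 changed by 1.58 ± 0.0685 in MIG and 1.17 ± 0.0681 in IK6 and Dhrs3 by -0.72 ± 0.136 in MIG and -0.62 ± 0.135 in IK6.

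With bexarotene, 5986 genes passed the threshold (3125 up, 2861 down, 1127 by at least 2-fold) in MIG and 6555 genes passed the threshold (3503 up, 3052 down, 1298 by at least 2-fold) in IK6. Among the largest changes, Tspan15 rose from 1.40 ± 0.323 to 51.9 ± 5.51 CPM in MIG and from 0.940 ± 0.189 to 34.8 ± 1.75 CPM in IK6, and Soat2 (ENSMUSG00000023045), an enzyme that esterifies cholesterol, from 0.489 ± 0.194 to 8.46 ± 1.96 CPM in MIG and from 0.943 ± 0.095 to 17.7 ± 1.93 CPM in IK6. In MIG, Ngfr changed by 7.02 ± 0.293, Itgad (ENSMUSG00000070369), an integrin chain, by 4.25 ± 0.43 and Fam129a (ENSMUSG00000026483) by 4.12 ± 0.132, and in IK6 Ostn (ENSMUSG00000052276), osteocrin, by 6.07 ± 0.542. Ratios in IK6 were 225 (39.8 to 8950) for Pdk4 and 78.5 (21.2 to 657) for Ngfr. Falls in MIG were -3.30 ± 0.154 for Mc1r, -3.25 ± 0.346 for Tph1 (ENSMUSG00000040046), tryptophan hydroxylase, -3.16 ± 0.366 for Gipr (ENSMUSG00000030406), an incretin receptor, and -3.07 ± 0.332 for Dnm1 (ENSMUSG00000026825), a dynamin. In IK6 they were -4.10 ± 0.318 for Cd6, -3.82 ± 0.334 for Slc35d3, -2.97 ± 0.199 for C4bp (ENSMUSG00000026405), a complement regulator, -3.29 ± 0.283 for Ighv14-2 (ENSMUSG00000076658) and -4.07 ± 1.17 for Hist1h2af, the last pair uncertain for their near copies.

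For the interaction of vector and bexarotene, 15 of 30 cell cycle genes had the lower response in IK6 and 12 of 21 glycolysis genes the higher, though neither list call held with an estimated correlation. Of cell cycle genes, 0 of 30 were shifted up and 15 down (21 over the list alone, adjusted p = 8e-24, adjusted p = 0.0536 with an estimated correlation). Ccna2 went from 134 ± 4.58 to 78.9 ± 2.17 CPM in MIG and from 182 ± 4.91 to 60.8 ± 4.26 CPM in IK6. Of glycolysis genes, 12 of 21 were shifted up and 0 down (18 over the list alone, adjusted p = 8.22e-17, adjusted p = 0.0826 with an estimated correlation). Slc16a3 differed by 1.18 ± 0.227. Of JAK-STAT and ERK genes, 6 of 22 were shifted up and 2 down (9 over the list alone, adjusted p = 0.00207, adjusted p = 0.544 with an estimated correlation). Pim2 differed by 1.27 ± 0.146. In all, 894 genes differed, 492 with the higher response in IK6 (55%, and 49.4% without IK6 bexarotene replicate 3, 49.8% without a filter and 49.6% with the covariate). They include Glt25d2 (ENSMUSG00000032649) (2.29 ± 0.221), Megf6 (ENSMUSG00000057751) (2.19 ± 0.166), the growth factor Tgfa (ENSMUSG00000029999) (2.06 ± 0.303), the calcium channel gene Cacna1i (ENSMUSG00000022416) (-2.28 ± 0.23) and Ighv1-54 (ENSMUSG00000076716) (-2.45 ± 0.566, uncertain for its near copies). Without IK6 bexarotene replicate 1 there were 575 such genes and Ighv1-54 was not among them (adjusted p = 0.11), and with the ribosomal protein covariate 2091.

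ATRA and bexarotene are both retinoids given at 1 µM, so they were compared directly. ATRA has a polyene chain ending in a carboxylic acid, while bexarotene joins a methylated tetralin ring to a benzoic acid. LXR and RXR target genes stood lower with bexarotene than with ATRA (10 of 14 in MIG and 11 of 14 in IK6), and stress response genes higher (12 of 20 and 10 of 20). The log2 difference, bexarotene minus ATRA, was -5.71 ± 0.0796 in MIG and -5.38 ± 0.0785 in IK6 for Abcg1, -3.90 ± 0.15 in MIG and -1.97 ± 0.134 in IK6 for Tgm2 and -3.43 ± 0.224 in MIG and -2.43 ± 0.259 in IK6 for Cyp26a1. It was -1.04 ± 0.117 in MIG and -0.48 ± 0.115 in IK6 for Cdkn1a and 2.33 ± 0.0669 in MIG and 2.46 ± 0.0659 in IK6 for Ddit3.

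Of LXR and RXR target genes, 0 of 14 stood higher and 10 lower (10 over the list alone, adjusted p = 1.56e-94) in MIG. In IK6, 1 stood higher and 11 lower (12 over the list alone, adjusted p = 3.08e-101), with medians of -1.46 and -1.68. Of cholesterol synthesis genes, 0 of 20 stood higher and 20 lower (20 over the list alone, adjusted p = 2.42e-40) in MIG. In IK6, 0 stood higher and 20 lower (20 over the list alone, adjusted p = 6.6e-37). Of retinoic acid response genes, 1 of 16 stood higher and 9 lower (10 over the list alone, adjusted p = 1.34e-14) in MIG. In IK6, 0 stood higher and 7 lower (7 over the list alone, adjusted p = 1.12e-11). Of stress response genes, 12 of 20 stood higher and 3 lower (17 over the list alone, adjusted p = 1.89e-26) in MIG. In IK6, 10 stood higher and 3 lower (14 over the list alone, adjusted p = 5.11e-19). Of cell cycle genes, 27 of 30 stood higher and 0 lower (27 over the list alone, adjusted p = 1.03e-19) in MIG. In IK6, 12 stood higher and 0 lower (13 over the list alone, adjusted p = 0.0119, adjusted p = 0.585 with an estimated correlation). Of MYC target genes, 7 of 20 stood higher and 0 lower (7 over the list alone, adjusted p = 0.048, adjusted p = 0.609 with an estimated correlation, 0.282 without the 3 libraries) in MIG. In IK6, 0 stood higher and 8 lower (9 over the list alone, adjusted p = 0.000469, adjusted p = 0.297 with an estimated correlation). Myc differed by -0.48 ± 0.0606 in IK6 and by 0.14 (95% interval 0.022 to 0.27) in MIG (adjusted p = 0.0808). A further 4 lists were called in MIG, downward for adhesion genes, JAK-STAT and ERK genes, glycolysis genes and interferon response genes (adjusted p = 2.68e-10 to 0.0359; adjusted p = 0.108 to 0.264 with an estimated correlation for all but interferon response genes). Calls lost under an alternative were those of adhesion genes (0.0676 without the 3 libraries, 0.0554 with the covariate). A further 4 lists were called in IK6, downward for adhesion genes, JAK-STAT and ERK genes, interferon response genes and MHC class II genes (adjusted p = 1.12e-06 to 0.0166; adjusted p = 0.0504 to 0.353 with an estimated correlation). Pim1 (ENSMUSG00000024014), a kinase induced by STAT5, differed by -1.13 ± 0.0602 in MIG and -0.78 ± 0.0596 in IK6. No difference was called for Plin2 (ENSMUSG00000028494), a lipid droplet coat protein, at 0.24 (95% interval -0.03 to 0.51) in MIG and 0.27 (95% interval 0.005 to 0.54) in IK6 (adjusted p = 0.213 and 0.149).

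Between the 2 retinoids, 3705 genes differed in MIG and 3441 in IK6. In MIG the largest differences included 4.83 ± 0.244 for Soat2, 4.69 ± 0.144 for Fam129a, 4.61 ± 0.192 for Cox6a2 (ENSMUSG00000030785), a subunit of cytochrome c oxidase, and -5.36 ± 0.265 for Mmp9. Abca1 was higher with ATRA by a ratio of 359 (123 to 1740) in MIG and 402 (137 to 1950) in IK6. In IK6, Ostn was higher with bexarotene by a ratio of 115 (38.7 to 561), a call lost in DESeq2 (adjusted p = 0.0692), and Wwtr1 (ENSMUSG00000027803), the cofactor TAZ, by 73.1 (24.5 to 359), and Clec7a differed by -5.35 ± 0.365. With the ribosomal protein covariate 5985 genes passed in MIG and 5838 in IK6, and 5501 passed in IK6 when only these groups were fitted. The covariate also made calls of Myc in MIG (adjusted p = 0.027) and of Plin2 in both vectors (adjusted p = 0.0011 in MIG and 7.64e-05 in IK6), and Plin2 in IK6 was called when only these groups were fitted (adjusted p = 0.000438) or without the 3 libraries (adjusted p = 0.00889).

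Carbacyclin, known as a ligand of the prostacyclin receptor and of PPAR delta, was compared with DMSO in each vector. In IK6, 12 of 18 PPAR target genes of fatty acid oxidation rose and 0 fell. In MIG 11 rose and 2 fell, and the list call there did not hold with an estimated correlation (adjusted p = 0.399). Cpt1a rose from 51.2 ± 1.97 to 266 ± 12 CPM in MIG and from 51.3 ± 2.26 to 269 ± 10.6 CPM in IK6, and Slc25a20 (ENSMUSG00000032602), the carnitine carrier of mitochondria, from 6.48 ± 0.906 to 60.5 ± 17.3 CPM in MIG and from 7.20 ± 0.59 to 56.6 ± 3.68 CPM in IK6. Tgm2 rose from 9.34 ± 1.37 to 281 ± 52.9 CPM in MIG and from 17.5 ± 1.12 to 273 ± 39.3 CPM in IK6. Cd22 (ENSMUSG00000030577), an inhibitory B cell receptor, fell from 352 ± 25.9 to 77.2 ± 6.65 CPM in MIG and from 286 ± 8.33 to 102 ± 7.69 CPM in IK6, and Rag1 rose from 8.50 ± 0.745 to 37.4 ± 5.5 CPM in MIG and from 17.8 ± 1.99 to 68.5 ± 3.34 CPM in IK6.

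Of PPAR target genes, 11 of 18 rose and 2 fell (14 over the list alone, adjusted p = 0.000118, adjusted p = 0.399 with an estimated correlation) in MIG. In IK6, 12 rose and 0 fell (12 over the list alone, adjusted p = 2.27e-13). Pdk4 had 0 counts with DMSO in MIG and 0.956 ± 0.0496 CPM with carbacyclin, at least 42.5-fold higher, and Angptl4 (ENSMUSG00000002289), a lipase inhibitor, changed by 0.50 ± 0.198 in MIG and 2.58 ± 0.215 in IK6. The call of Angptl4 in MIG was lost without carbacyclin replicate 4 (log2 change 0.215, adjusted p = 0.307) and without DMSO replicate 1, 2 or 4 (adjusted p = 0.0811, 0.0774 and 0.114). It was also lost without the 3 libraries of high ribosomal protein share, with a replicate term and when only these groups were fitted (adjusted p = 0.0817, 0.0512 and 0.2). Of interferon response genes, 16 of 23 rose and 0 fell (17 over the list alone, adjusted p = 0.000491, adjusted p = 0.249 with an estimated correlation) in MIG. In IK6, 22 rose and 0 fell (22 over the list alone, adjusted p = 8.15e-31). Rtp4 (ENSMUSG00000033355) changed by 2.13 ± 0.173 in MIG and 4.06 ± 0.219 in IK6. Of cholesterol synthesis genes, 1 of 20 rose and 14 fell (15 over the list alone, adjusted p = 0.000538, adjusted p = 0.437 with an estimated correlation) in MIG. In IK6, 1 rose and 10 fell (11 over the list alone, adjusted p = 0.0155, adjusted p = 0.622 with an estimated correlation). Lss (ENSMUSG00000033105), lanosterol synthase, changed by -1.02 ± 0.077 in MIG and -0.67 ± 0.0834 in IK6. Of pre-B and B-lineage genes, 13 of 20 rose and 2 fell (16 over the list alone, adjusted p = 0.011, adjusted p = 0.399 with an estimated correlation) in MIG. In IK6, 8 rose and 2 fell (11 over the list alone, adjusted p = 0.219). Blnk (ENSMUSG00000061132), a pre-B adaptor, changed by 0.72 ± 0.0464 and Igll1 (ENSMUSG00000075370), a surrogate light chain gene, by 0.70 ± 0.105 in MIG. In IK6, of nuclear receptor genes 5 of 13 rose and 1 fell (6 over the list alone, adjusted p = 0.000843, adjusted p = 0.0508 with an estimated correlation). Vdr (ENSMUSG00000022479), the vitamin D receptor, changed by 5.16 ± 0.167 and Nr4a3 (ENSMUSG00000028341) by 3.99 ± 0.226 in IK6. Of retinoic acid response genes in IK6, 5 of 16 rose and 1 fell (6 over the list alone, adjusted p = 0.0163), with a median of -0.03, opposite in sign to the test. Of LXR and RXR target genes in IK6, 4 of 14 rose and 2 fell (7 over the list alone, adjusted p = 0.0454, adjusted p = 0.279 with an estimated correlation, 0.058 with replicate blocks, 0.0639 without the 3 libraries, 0.0696 with the covariate). Abcg1 changed by 1.65 ± 0.0606 there. Of MYC target genes in IK6, 10 of 20 rose and 0 fell (10 over the list alone, adjusted p = 0.0454, adjusted p = 0.622 with an estimated correlation). Myc changed by 0.45 ± 0.0596 there. A further 2 lists were called in MIG, downward for glycolysis genes and stress response genes (adjusted p = 7.59e-10 and 0.011; adjusted p = 0.249 and 0.566 with an estimated correlation). A further 2 lists were called in IK6, upward for stromal and endothelial markers and downward for T and NK cell markers (adjusted p = 0.00102 and 0.00928).

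With carbacyclin, 7536 genes passed the threshold (3878 up, 3658 down, 1827 by at least 2-fold) in MIG and 6218 genes passed the threshold (3259 up, 2959 down, 1489 by at least 2-fold) in IK6. In MIG, Dmbt1 (ENSMUSG00000047517) changed by 7.23 ± 0.307, Crisp3 (ENSMUSG00000025433) by -5.77 ± 0.2, Cox6a2 by -4.78 ± 0.309 and Cd28 by -4.65 ± 0.288, and Ret (ENSMUSG00000030110), a receptor tyrosine kinase, rose by a ratio of 161 (54.8 to 783). In IK6, Slc26a9 (ENSMUSG00000042268), an anion transporter, rose by a ratio of 1880 (337 to 74400) and Pdk4 by 790 (141 to 31300). Apol7c (ENSMUSG00000044309), uncertain for its near copies, had 0 counts with DMSO and 2 ± 0.61 CPM with carbacyclin, at least 104-fold higher. Slpi (ENSMUSG00000017002), a protease inhibitor, changed by -5.15 ± 0.267, Slc17a8 (ENSMUSG00000019935), a glutamate transporter, by -5.12 ± 0.167 and Crisp3 by -4.41 ± 0.177. When only the compared groups were fitted, 4710 genes passed in MIG.

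For the interaction of vector and carbacyclin, interferon genes (19 of 23) and glycolysis genes (16 of 21) had the higher response in IK6. Of interferon response genes, 19 of 23 were shifted up and 0 down (22 over the list alone, adjusted p = 2.68e-35), with a median of 1.30. Mx1 went from 1.51 ± 0.404 to 1.35 ± 0.116 CPM in MIG and from 0.223 ± 0.0471 to 2.15 ± 0.259 CPM in IK6. Of glycolysis genes, 16 of 21 were shifted up and 0 down (20 over the list alone, adjusted p = 1.55e-24), with a median of 0.88. Slc2a3 (ENSMUSG00000003153), a glucose transporter, went from 45.0 ± 3 to 25.4 ± 1.31 CPM in MIG and from 26.4 ± 0.78 to 40.8 ± 7.49 CPM in IK6. Of T and NK cell markers, 0 of 9 were shifted up and 3 down (4 over the list alone, adjusted p = 0.00556). Cd5 differed by -1.96 ± 0.244. Of PPAR target genes, 5 of 18 were shifted up and 0 down (5 over the list alone, adjusted p = 0.00651, adjusted p = 0.532 with an estimated correlation). Angptl4 differed by 2.08 ± 0.293. Of nuclear receptor genes, 4 of 13 were shifted up and 0 down (5 over the list alone, adjusted p = 0.04, adjusted p = 0.462 with an estimated correlation, 0.0606 with replicate blocks, 0.115 without the 3 libraries, 0.148 with the covariate), with a median of -0.019, opposite in sign to the test. A further 4 lists were called, upward for cell cycle genes, cholesterol synthesis genes and stress response genes and downward for pre-B and B-lineage genes (adjusted p = 0.000457 to 0.04; adjusted p = 0.462 to 0.634 with an estimated correlation). Calls lost under an alternative were those of cholesterol synthesis genes (0.0523 with replicate blocks).

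In all, 1386 genes differed in their carbacyclin response, 889 with the higher response in IK6. Slc26a9 went from 0.0275 ± 0.0334 to 0.123 ± 0.0513 CPM in MIG and from 0.00803 ± 0.0161 to 12.0 ± 0.957 CPM in IK6, and Lrrc55 (ENSMUSG00000075224) from 0.0239 ± 0.0305 to 0 ± 0 CPM in MIG and from 0.0805 ± 0.034 to 1.97 ± 0.332 CPM in IK6. Pdgfrb (ENSMUSG00000024620), a receptor of platelet-derived growth factor, went from 0.0160 ± 0.0321 to 0.0427 ± 0.00839 CPM in MIG and from 0.0244 ± 0.0205 to 4.50 ± 0.876 CPM in IK6. The growth factor receptor Fgfr2 (ENSMUSG00000030849) differed by -3.40 ± 0.36, Dmbt1 by -2.68 ± 0.539 and Slc17a8 by -2.22 ± 0.217. Pdgfrb lost its call without MIG DMSO replicate 1 (adjusted p = 0.948) and with only the 4 groups fitted (adjusted p = 0.0531), and Lrrc55 without MIG DMSO replicate 2 (adjusted p = 0.0634). Fitting only the 4 groups gave 884 genes and the ribosomal protein covariate 2853, while leaving out MIG carbacyclin replicate 4 gave 2521, 51.6% of them higher in IK6 instead of 64.1%, and leaving out the 3 libraries 2253 (57.3%).

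NOE, known as a ligand of PPAR alpha and an inhibitor of ceramidase, was compared with DMSO in each vector. Cell cycle genes fell (30 of 30 in both vectors) and the recombinase genes rose. Ccna2 fell from 134 ± 4.58 to 35.7 ± 3.15 CPM in MIG and from 182 ± 4.91 to 81.5 ± 2.83 CPM in IK6. Rag1 rose from 8.50 ± 0.745 to 74.6 ± 6.85 CPM in MIG and from 17.8 ± 1.99 to 100.4 ± 8.57 CPM in IK6, and Rag2 (ENSMUSG00000032864), its partner, from 2.12 ± 0.224 to 10.3 ± 0.676 CPM in MIG and from 2.37 ± 0.302 to 8.60 ± 0.886 CPM in IK6. Cd22 fell from 352 ± 25.9 to 50.2 ± 1.09 CPM in MIG and from 286 ± 8.33 to 67.2 ± 3.82 CPM in IK6.

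Of cell cycle genes, 0 of 30 rose and 30 fell (30 over the list alone, adjusted p = 4.03e-49) in MIG. In IK6, 0 rose and 30 fell (30 over the list alone, adjusted p = 1.23e-37). Of pre-B and B-lineage genes, 13 of 20 rose and 3 fell (18 over the list alone, adjusted p = 0.00112, adjusted p = 0.2 with an estimated correlation) in MIG. In IK6, 13 rose and 4 fell (17 over the list alone, adjusted p = 0.00563, adjusted p = 0.262 with an estimated correlation). Blnk changed by 1.01 ± 0.0465 in MIG and 0.94 ± 0.0465 in IK6. Of interferon response genes, 15 of 23 rose and 4 fell (20 over the list alone, adjusted p = 0.00953, adjusted p = 0.279 with an estimated correlation) in MIG. In IK6, 20 rose and 1 fell (21 over the list alone, adjusted p = 4.7e-09). Usp18 (ENSMUSG00000030107) changed by 0.98 ± 0.0996 in MIG and 1.55 ± 0.106 in IK6. Of MYC target genes, 0 of 20 rose and 15 fell (16 over the list alone, adjusted p = 0.00271, adjusted p = 0.542 with an estimated correlation) in MIG. In IK6, 1 rose and 13 fell (15 over the list alone, adjusted p = 0.00101, adjusted p = 0.387 with an estimated correlation). Nolc1 changed by -0.64 ± 0.0475 in MIG and -0.88 ± 0.0475 in IK6, while Myc changed by 0.34 ± 0.0555 in IK6. Cpt1a changed by -0.68 ± 0.0501 in MIG. Of myeloid markers, 5 of 12 rose and 2 fell (7 over the list alone, adjusted p = 0.0131, adjusted p = 0.174 with an estimated correlation) in MIG. Itgam (ENSMUSG00000030786), the CD11b chain, changed by 1.69 ± 0.107 and Lyz2 by 3.01 ± 0.279 there. Of retinoic acid response genes, 8 of 16 rose and 1 fell (9 over the list alone, adjusted p = 0.025, adjusted p = 0.0559 with an estimated correlation) in IK6. Tgm2 changed by 2.76 ± 0.128 in MIG and 2.19 ± 0.122 in IK6. Of glycolysis genes, 1 of 21 rose and 1 fell (2 over the list alone, adjusted p = 0.634) in MIG. In IK6, 20 rose and 0 fell (21 over the list alone, adjusted p = 3.36e-06, adjusted p = 0.321 with an estimated correlation). Pdk1 changed by 0.97 ± 0.0751 in IK6. Cholesterol synthesis and stress response genes were also called downward in MIG (adjusted p = 0.00391 and 0.0131, 0.542 and 0.664 with an estimated correlation). In IK6 cholesterol synthesis genes were (adjusted p = 0.025, 0.486 with an estimated correlation).

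With NOE, 7050 genes passed the threshold (3547 up, 3503 down, 1737 by at least 2-fold) in MIG and 6425 genes passed the threshold (3575 up, 2850 down, 1369 by at least 2-fold) in IK6. In MIG, Eya2 (ENSMUSG00000017897), a transcriptional cofactor, changed by 3.48 ± 0.164, Serpinb9c (ENSMUSG00000021404), uncertain for its near copies, by 3.60 ± 0.142, Enpp6 (ENSMUSG00000038173), a choline phosphodiesterase, by -7.37 ± 0.165 and Slco5a1 (ENSMUSG00000025938) by -5.73 ± 0.191, and Hbb-bh1 fell by a ratio of 121 (33.1 to 1010). In IK6, Stc1 (ENSMUSG00000014813), stanniocalcin, changed by 3.78 ± 0.122, the adhesion receptor genes Gpr110 (ENSMUSG00000041293) and Gpr116 (ENSMUSG00000056492) by 3.61 ± 0.178 and 3.56 ± 0.345, Ccr6 (ENSMUSG00000040899), a chemokine receptor, by -5.98 ± 0.161 and Hbb-bh1 by -5.88 ± 0.411.

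For the interaction of vector and NOE, glycolysis genes (17 of 21) and interferon genes (10 of 23) again had the higher response in IK6. Of glycolysis genes, 17 of 21 were shifted up and 0 down (21 over the list alone, adjusted p = 7.16e-21), with a median of 0.77. Slc2a3 went from 45.0 ± 3 to 50.4 ± 6.07 CPM in MIG and from 26.4 ± 0.78 to 63.7 ± 4.17 CPM in IK6. Of interferon response genes, 10 of 23 were shifted up and 0 down (14 over the list alone, adjusted p = 1.6e-07), with a median of 0.59. Mx1 went from 1.51 ± 0.404 to 0.764 ± 0.171 CPM in MIG and from 0.223 ± 0.0471 to 0.580 ± 0.165 CPM in IK6. Of cell cycle genes, 13 of 30 were shifted up and 0 down (15 over the list alone, adjusted p = 2.61e-11, adjusted p = 0.225 with an estimated correlation). Ccna2 differed by 0.75 ± 0.0892. A further 2 lists were called, upward for PPAR target genes and stress response genes (adjusted p = 0.000828 and 0.0311; adjusted p = 0.492 and 0.538 with an estimated correlation). Calls lost under an alternative were those of PPAR target genes (0.0849 without the 3 libraries, 0.126 with the covariate). In all, 1385 genes differed, 1039 with the higher response in IK6 (75%, and 60.9% with CPM above 1 and 60% without the 3 libraries). They include Enpp6 (4.11 ± 0.237), the adhesion adaptor Bcar1 (ENSMUSG00000031955) (3.12 ± 0.332), Adm (ENSMUSG00000030790), adrenomedullin (2.58 ± 0.413), Smoc1 (ENSMUSG00000021136) (-2.99 ± 0.308), Fgfr2 (-2.74 ± 0.305) and Gcnt2 (ENSMUSG00000021360) (-2.46 ± 0.389). The ribosomal protein covariate gave 2693 genes. All 4 interactions share the DMSO groups.

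**Figure D4:**
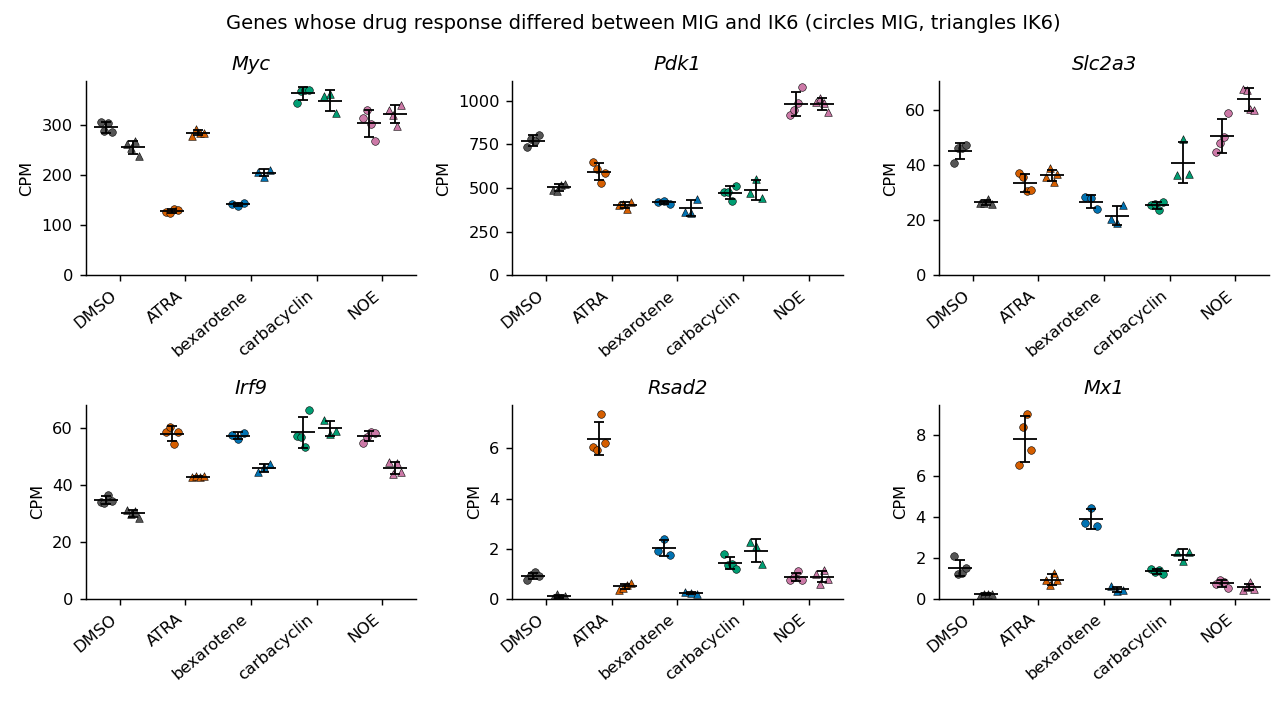
CPM (y axes) of 6 genes with a different drug response in IK6 and MIG, in each library of the 10 groups (x axes). Circles are MIG, triangles IK6, bars the group mean and whiskers the SD, and Myc averages 296 CPM with DMSO and 128 CPM with ATRA in MIG, against 255 and 285 CPM in IK6.

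**Figure D5:**
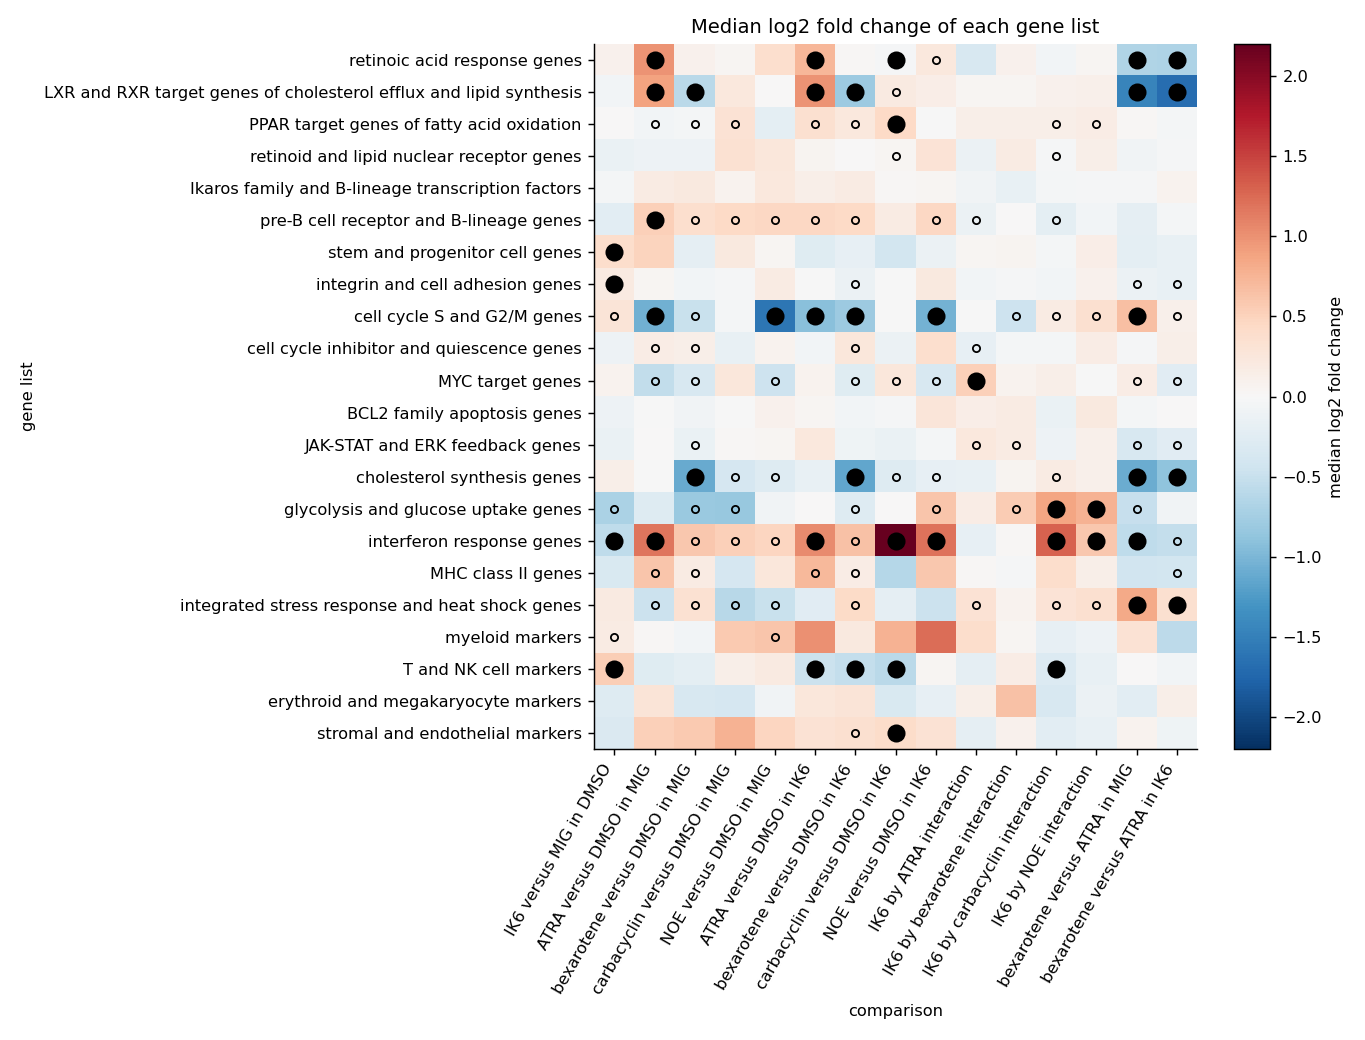
Median log2 fold change (colour) of the 22 gene lists (y axis) in the 15 comparisons (x axis). Large filled circles mark camera calls that held with an estimated correlation (44 of 122), and small open circles those that did not.

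Each compound moved largely shared genes in the 2 vectors, which have no libraries in common. For ATRA, 4375 genes were called in the same direction in MIG and IK6, where independent responses would give 1429, and 142 in opposite directions (1431 if independent). The same-direction counts were 4264 for bexarotene (1253 if independent), 4712 for carbacyclin (1495) and 4684 for NOE (1444). Pearson's r of the log2 fold changes was 0.727, 0.719, 0.749 and 0.768 across genes, which are not independent replicates. ATRA and bexarotene shared 4006 genes in MIG (1251 if independent) and 4438 in IK6 (1431). These pairs share the DMSO libraries: the covariance was 0.289 in MIG and 0.301 in IK6, against 0.0336 and 0.0284 in simulated unchanged groups, and r was 0.679 and 0.701 against 0.462 and 0.448. With the DMSO libraries parted between the comparisons, 2898 and 3246 genes were shared, with r of 0.539 and 0.625.

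The difference between IK6 and MIG was also set against the response of IK6 cells to each compound. With the NOE libraries supplying the vector difference, so that no library is shared, ATRA moved 2198 genes against it and 950 along with it, where independence would give 1107 and 1122. Bexarotene moved 2163 against (1057 if independent) and 782 along (1080), carbacyclin 1641 against (1006) and 1145 along (1021). Across genes r was -0.074, -0.137 and 0.065. With the DMSO libraries in both comparisons the counts against and along were 1590 and 910 for ATRA, 1599 and 761 for bexarotene and 1271 and 1065 for carbacyclin. With these libraries parted between them they were 1009 and 646, 1040 and 512, and 827 and 749, with r of -0.032, -0.096 and 0.044. Carbacyclin and NOE, a pair chosen after seeing the data, shared 3592 genes in MIG (1692 if independent, 2694 with the controls parted) and 2669 in IK6 (1279, and 1978). Their r of 0.528 and 0.476 compares with 0.539 and 0.456 in simulated unchanged groups, and their covariance of 0.306 and 0.236 with 0.0348 and 0.0295.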

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

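Chosen only after the results were seen were the tests of exchanged labels, of the 3 libraries with a high ribosomal protein share and of separate cell clones. The tests of the V locus and of low oxygen were set up after these patterns were seen, before their own values were. The test of other splits of the libraries was planned. Of 107 tests of 1 library against the rest of its group of 4, 11 found a library far from the others, in 5 of the 7 groups tested, where about 5% arise by chance.

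MIG with DMSO replicate 3 stood apart in its ribosomal protein share (15.71% against 9.482 to 10.07%), in Cdkn2a (115.4 against 61.62 to 67.74 CPM) and in Igll1 (1005 against 742 to 766.3 CPM). MIG with carbacyclin replicate 4 had 78.17 CPM of Ikzf3 against 138.5 to 149.3, and replicate 1 had 344.6 CPM of Myc against 368.9 to 369.5. In MIG with ATRA, replicate 3 had a total of 16.5 (in units of 1000000 counts) against 33.3 to 34.2, replicate 2 had 65.69 CPM of Cdkn2a against 83.81 to 87.03, and replicate 1 had 39.32 CPM of Plin2 against 34.03 to 34.78. Further single libraries were MIG with DMSO replicate 2 (a total of 48 in the same units against 29.4 to 31.1), MIG with NOE replicate 3 (83.42 CPM of Abcg1 against 76.89 to 77.84) and IK6 with DMSO replicate 1 (218.9 CPM of Ikzf3 against 196.2 to 199.9).

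The response to each compound differed between the vectors by the interaction test: 1536 genes for ATRA, 894 for bexarotene, 1386 for carbacyclin and 1385 for NOE. Among lists whose interaction also passed with an estimated correlation, the median log2 difference was 0.529 for MYC target genes with ATRA, -0.309 for T and NK cell markers with carbacyclin, 1.304 and 0.586 for interferon response genes with carbacyclin and NOE, and 0.876 and 0.772 for glycolysis genes with carbacyclin and NOE.

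LXR and RXR target genes and cholesterol synthesis genes were lower with bexarotene than with ATRA, in both vectors. Exchanged labels of the 2 compounds would put the retinoic acid response genes higher in the libraries named bexarotene, and their median difference was -0.665 in MIG and -0.673 in IK6, which argues against it. Without the 3 libraries of high ribosomal protein share the LXR and RXR list stayed lower in MIG (adjusted p = 2.17e-75). This argues against them as the source there, and the IK6 comparison holds none. A different action of the 2 compounds stays open, found and tested on the same data.

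Several heavy chain V segments were near 0 in IK6 and expressed in MIG. Loss of a locus stretch could group segments of the same direction. Such neighbouring pairs numbered 8 (median 8, 95th percentile 12 in permuted orders, one-sided permutation p = 0.679). Only called segments entered, so loss stays open. Of 18 called among 28 tested segments, 11 were higher and 7 lower in IK6. Separate cell clones under the vectors may account for this: 15 of the 18 kept their direction in all 5 treatments, but clone and vector cannot be told apart in this design, since each vector stands for 1 population or several of unknown origin. Reads shared between near-identical segments were not tested.

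Glycolysis genes were higher after carbacyclin and NOE in IK6 than in MIG, relative to DMSO. Without the 3 libraries of high ribosomal protein share the adjusted p was 3.65e-31 for carbacyclin and 9.21e-24 for NOE, which argues against these libraries as the source. A candidate explanation is a difference in oxygen supply, for example by culture density: 18 hypoxia genes outside the glycolysis list had median interactions of 0.928 for carbacyclin (12 up, 1 down, 15 adjusted over the list alone, camera p = 7.71e-26, p = 1.74e-05 with an estimated correlation) and 0.808 for NOE (11 up, 0 down, 13 adjusted over the list alone, camera p = 1.26e-19, p = 0.000125 with an estimated correlation). The same genes were lower in IK6 than in MIG with DMSO, with a median of -0.524 (camera p = 5.14e-07, p = 0.0197 with an estimated correlation), and with carbacyclin they fell in MIG (median -0.864) and were not called as a list in IK6 (median -0.053). An effect of IK6 on the response to these compounds stays open and was not tested apart from it.

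In splits of the libraries of the 11 comparisons of 2 groups, fitted alone, only 1 of 35, the real one, gave as many genes. This does not exclude chance, since the other splits mix the 2 groups. The real split gave 4420 genes for IK6 against MIG in DMSO, and 6288, 5048, 4710 and 6524 in MIG and 9849, 8845, 7724 and 6633 in IK6 for ATRA, bexarotene, carbacyclin and NOE, and the highest other split gave 0 in each. For bexarotene against ATRA it gave 3304 genes in MIG and 5501 in IK6, with 7 and 2 in the highest other split. For the interactions the splits decide nothing, since exchanges within 1 vector may turn the response common to both vectors into a difference. There 100 splits were drawn with labels exchanged within each vector, and 1 split for ATRA, 3 for bexarotene, 2 for carbacyclin and 3 for NOE gave as many genes. The real values were 2530, 1054, 884 and 1260, and the highest others 1590, 7335, 1390 and 4666. The highest splits for bexarotene and NOE largely reverse the labels of 1 vector. The first exchanges 3 of 4 DMSO labels in MIG and 0 in IK6, the second 4 of 4 in IK6 and 1 in MIG.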

How the results depend on the processing

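Chosen only after the data were seen were leaving out the 3 libraries of high ribosomal protein share, that share as a covariate, and the overlap of carbacyclin and NOE. Counts of genes stayed within 1.5 times the reported value in all 15 comparisons with DESeq2, the other scalings, the other filters and the replicate block, and no gene called both ways turned direction. The replicate numbers do not pair the libraries: 42 of 156 pairs with the same number correlated above 0.1, with a median of -0.018, against a median of 0.008 over 459 other pairs. Scaling moved the median log2 change of all genes by at most 0.047 in size, from -0.047 to 0.043 with upper-quartile scaling.

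With the ribosomal protein covariate the count was 6626 for IK6 against MIG in DMSO, 2713, 2091, 2853 and 2693 for the interactions with ATRA, bexarotene, carbacyclin and NOE, and 5985 in MIG and 5838 in IK6 for bexarotene against ATRA. With fits of the compared groups alone it was 4710 for carbacyclin in MIG, 2530 and 884 for the interactions with ATRA and carbacyclin, and 5501 for bexarotene against ATRA in IK6. Without the 3 libraries it was 2253 for the carbacyclin interaction. Leaving out each library in turn gave 575 to 828 genes for the bexarotene interaction, the lowest without IK6 bexarotene replicate 1, and 1152 to 2521 for the carbacyclin interaction, the highest without MIG carbacyclin replicate 4. In the other 13 comparisons it stayed within 1.5 times. The cause of these changes was not tested. Except for IK6 against MIG in DMSO, NOE in each vector and the carbacyclin and NOE interactions, the larger of the 2 directions of change turned under some alternative.

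Of 330 list tests 122 passed, 118 with the replicate block, 123 without the 3 libraries and 123 with the covariate, of which 117, 114 and 114 were among the 122. With an estimated correlation 44 passed and with fry 222, which does not compare a list with other genes. The correlation of ATRA and bexarotene responses in MIG was 0.539 with halved controls against 0.679. The vector ratio of Ikzf1 was 1.72 with scaling by totals alone against 1.61. Of 277 gene results the text names, 0 turned direction in 4889 repeats, and 12 repeats over 5 of them lost the call.
Depth limits genes near 0, whose ratios have wide counting intervals. In counts simulated for all 37 libraries, ATRA was tested against DMSO in MIG, with 4 libraries each. There 1.5-fold changes were found in 68.7% of genes and 2-fold changes in 95.5%. Depth was not varied, and groups of 3 and interactions were not simulated.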

Other observations

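The test of low oxygen in the other interactions was added after the results for glycolysis genes were seen. Further values of the 18 hypoxia genes outside the glycolysis list follow. With NOE in IK6, 17 rose and 0 fell (17 adjusted over the list alone, camera p = 1.09e-09, p = 0.00556 with an estimated correlation), with a median log2 change of 0.814. With carbacyclin in MIG, 3 rose and 15 fell (18 adjusted over the list alone, camera p = 2.63e-09, p = 0.00635 with an estimated correlation), with a median of -0.864, and with carbacyclin in IK6 4 rose and 3 fell (7 adjusted over the list alone, camera p = 0.635), with a median of -0.053. With NOE in MIG 9 rose and 6 fell (15 adjusted over the list alone, camera p = 0.422), with a median of 0.129, and with bexarotene in MIG 1 rose and 14 fell (16 adjusted over the list alone, camera p = 6.09e-09, p = 0.0082 with an estimated correlation), with a median of -0.666. Medians were -0.289 and -0.111 with ATRA in MIG and IK6 and -0.08 with bexarotene in IK6, not called as lists. Interaction medians were 0.607 for bexarotene (12 up, 0 down, 13 adjusted over the list alone, camera p = 1.6e-14, p = 0.000782 with an estimated correlation) and 0.067 for ATRA (0 up, 0 down, 0 adjusted over the list alone, camera p = 0.812).

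Within groups, 69.5% of the variance over 8000 genes lay along a single axis of the residuals. The 3 libraries with a ribosomal protein share above 12% scored 34.56, 23.29 and 16.68 on it, and MIG with carbacyclin replicate 1, with the lowest share (7.485%), scored -19.37.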
